A study of Mus musculus with 2 samples.

How the data were processed

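The series holds 2 droplet single-cell RNA libraries from mouse lung, 1 from a wild-type (WT) and 1 from a p47phox-KI source, both of strain C57BL/6 and both labelled with acute lung injury. According to the labels, lungs were perfused, digested with collagenase, freed of erythrocytes by lysis, stained with a viability dye and an antibody to the leukocyte antigen CD45.2, and sorted. The sort gate is not stated, nor is the agent of injury, the number of animals behind each library or their sex. Libraries were made with the 10x Chromium V3 kit, which reads a tag near the 3' end of each transcript.

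The deposited files hold raw UMI counts, 1 matrix per library, as the whole-number entries and the matrix layout show. The submitters' processing notes name Cell Ranger 2.0, Seurat 2.3.4, R 3.5.3 and the mm10 genome. Per the file headers, the matrices were written by software version 3.0.2. No matrix held a barcode with fewer than 500 UMIs, so the authors' cell calling or a later filter had already removed shallow barcodes. The matrices list 31053 genes, of which 23425 had a UMI in either library. Gene positions come from GENCODE M21 on GRCm38, the assembly also called mm10, in which 30934 of the gene identifiers were found and 119 were not. The libraries share 30 barcode sequences, which were kept apart by library.

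Barcodes with fewer than 200 detected genes (92 in WT, 142 in KI) or with over 10% mitochondrial UMIs (2055 in WT, 1921 in KI) were left out, and so were barcodes marked as doublets. Doublets were scored with Scrublet in scanpy 1.11.5, separately for each library. Its automatic threshold marked 0 barcodes in both libraries. After this was seen, the threshold was replaced by the expected rate of 0.8% per 1000 barcodes, which marked the 877 highest-scored WT barcodes (8.37%) and 665 KI barcodes (7.29%). The alternative with doublets kept is therefore also the result of the automatic threshold. The filters left 7735 WT and 6636 KI cells.

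All 14371 kept cells were clustered together without batch integration. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes were chosen per library and combined. Xist, Tsix, Y-linked genes and variable segments of immunoglobulin and T cell receptor genes were left out of this choice. The first 30 principal components and 15 nearest neighbours gave a shared-neighbour graph, which Leiden clustering at resolution 1 divided into 33 clusters. A cluster took the class whose fixed markers had the highest mean log2 fold over the mean of the clusters. It stayed unnamed with fewer than 3 detected markers, with a mean score under 0.5, or with more markers of another class than of its own among its 10 leading genes. A cluster of low depth also stayed unnamed if none of its own markers were among those genes. The limit of 3 markers was added after some clusters had been named on fewer. The rule named 29 clusters, and names carry the suffix -like because they rest on markers alone.

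UMIs were summed per library and class and expressed as CPM, a gene's UMIs rescaled by all UMIs of the class. Classes with at least 100 cells in each library were compared. Ratios are log2 of KI over WT. Ratios carry exact conditional binomial 95% intervals, levels carry exact Poisson intervals, and shares of cells carry exact Clopper-Pearson intervals, all from scipy 1.17.1. A gene with 0 UMIs is given with the level that 3 counts would have. Intervals and limits cover counting error only. Because each group holds 1 library, there is no replicate check, and no test, standard error or count of changed genes is given.

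Markers and 27 gene lists were fixed before the data were examined. For each list and class, members with at least 20 UMIs in the class were measured, with 0.5 counts added to each sum. The list's median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the same 20 expression bins. Its percentile describes these 2 libraries and is no test across animals. The counting range of a median comes from 1000 Poisson resamples of the sums. Members are counted as higher or lower when their log2 ratio passed 0.5 in either direction. Results are printed for the lists discussed in each class, and those of the alveolar classes were chosen after their values were seen. The lists of each class are also summarised as counts.

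Named genes follow a rule fixed beforehand. In the 3 classes with the most cells, the rule takes the 10 highest and 10 lowest log2 ratios among genes with at least 50 CPM and a UMI in at least 10% of cells in either library. In the other classes it takes 3 in each direction. Sex-linked transcripts, mitochondrial, ribosomal protein and haemoglobin genes, receptor segments and unnamed gene models were left out of the ranking. The ranking also left out genes more than 20 times lower in the class than in another named class of the same library, a level that RNA released from other cells can reach. This limit was read in the library where the gene was higher, and it did not compare with unnamed clusters. In endothelial-like cells 3867 of 4053 genes were ranked, 31 having been left out for free RNA, 81 as ribosomal, 60 as gene models, 12 as mitochondrial and 2 as sex-linked. In fibroblast-like cells 3619 of 3803 genes were ranked, and in smooth muscle or pericyte-like cells 3863 of 4052. In type 2 alveolar cells 2309 of 2464 were ranked, and in type 1 alveolar cells 3771 of 3948. The rule adds Ncf1 and the other NADPH oxidase genes, and the 3 members of each discussed list with the largest absolute log2 ratio. For list members and oxidase genes the free-RNA limit does not exclude a gene, and the text says where a gene fell past it. Some items that the rule takes are not reported here.

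Each alternative changed 1 step of the processing. The stricter cell filter moved both of its limits together, and the weighting also left out clusters with few cells. Some kept doublets, required 500 genes and at most 5% mitochondrial UMIs, or applied no cell filter. Others used resolution 0.5 or 2, 50 principal components, or each library clustered alone. The scaling alternatives were edgeR 4.0.16 TMM factors and median-of-ratios factors. Further alternatives were the mean over cells of per-cell CPM, the same cluster weights in both libraries, list members with at least 100 UMIs or no minimum, 3 counts added, and cells thinned to 1000 UMIs. In the weighting, a cluster needed 20 cells in each library, which 10 of 12 endothelial-like clusters and 1 of 2 type 2 alveolar clusters had. A pair of alternatives was chosen after seeing the data: leaving out clusters whose median UMIs were under 50% of their library's, and leaving out barcodes with over 1% haemoglobin UMIs. The median gene shifted by at most 0.12 (log2) between CPM and either other scaling. That largest shift was in type 1 alveolar cells, and the others were 0.10 or less.

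The ratio and list methods were tested on simulated data made from the endothelial-like sums, with 200 of 12376 genes changed 2-fold. Counts were drawn as independent Poisson values around means shared by both libraries, as the intervals assume. The simulation therefore checks the computation only, and not the spread between cells, animals or libraries. The direction was right for 100% of changed genes, and the intervals held the true value for 95% of changed and 95.2% of unchanged genes. A list with 12 of 20 members raised reached percentile 100, and 5% of 200 unchanged lists fell outside the central 95% of random lists. Other tools were Python 3.11.15, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.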

Results

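The data are raw UMI counts from sorted cells of injured mouse lungs, 1 library from a WT source and 1 from a p47phox-KI source. The WT library holds 43376713 UMIs in 10473 barcodes and the KI library 43445797 UMIs in 9120 barcodes. Median depth per barcode was 2994 UMIs and 1540 genes in WT, and 3391 UMIs and 1689.5 genes in KI. The lowest barcode held 500 UMIs in each. After filtering, 7735 WT and 6636 KI cells remained, with medians of 3307 and 3774.5 UMIs and of 1692 and 1876.5 genes. The median mitochondrial share of kept cells was 4.65% in WT and 4.63% in KI. Haemoglobin RNA was found in 1.54% of WT and 17.2% of KI barcodes before filtering. Most kept cells carried endothelial, fibroblast, mural or alveolar epithelial markers, and leukocytes made up 3.12% of WT and 1.91% of KI cells.

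The stated purpose of the series is to set single-cell expression in WT lungs beside that in p47phox-KI lungs. The first question is how Ncf1 itself reads in the 2 libraries. Ncf1 (ENSMUSG00000015950, chromosome 5, 134220053 to 134229625, minus strand, GRCm38) encodes p47phox, the subunit that organises the phagocyte NADPH oxidase, the enzyme behind the oxidative burst. The labels do not say how the gene was modified, and a tag near the transcript's end can miss the modification. Ncf1 transcript was found in both libraries at similar levels. Over all barcodes there were 228 Ncf1 UMIs in WT and 213 in KI (5.26 and 4.90 CPM), a log2 ratio of −0.10 [95% counting interval −0.38, 0.18]. In kept cells the ratio was −0.16 [−0.48, 0.15], from 182 and 162 UMIs. The sign of this ratio turned with the same cluster weights in both libraries (0.38), and it was −1.38 as the mean of per-cell CPM.

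The Ncf1 level was highest in leukocytes, the cells in which the oxidase is known to work. Leukocyte clusters held 135 of the 182 WT and 90 of the 162 KI UMIs of kept cells. The other kept cells held 47 and 72 UMIs (1.44 and 2.21 CPM), a log2 ratio of 0.62 [0.07, 1.18]. Of these UMIs, 38 and 58 were in type 2 alveolar cells. Neutrophil-like cells held 444 CPM in WT (82 UMIs) and 290 CPM in KI (7 UMIs), a log2 ratio of −0.62 [−1.98, 0.49]. In cluster 24, an unnamed macrophage mixture led by Chil3, Ctss and complement component C1q genes, the levels were 194 and 225 CPM, a ratio of 0.21. B cell-like cells held 64.7 and 63.2 CPM. Over all leukocyte clusters the levels were 190 and 148 CPM, a ratio of −0.36 [−0.76, 0.04]. An Ncf1 UMI was found in 52.1% of WT and 45.5% of KI neutrophil-like cells, at median depths of 1699 and 1960 UMIs. Endothelial-like cells gave 0.110% and 0.208% at 3518.5 and 3978 UMIs, from 5 and 9 UMIs at a free-RNA level. Type 1 alveolar cells, an epithelial class, gave none at 2995 and 2502 UMIs. Type 2 alveolar cells held 6.38 and 8.27 CPM, more than 20 times lower than neutrophil-like cells, with a ratio of 0.37 [−0.24, 1.00], which became 1.59 under the stricter cell filter and −0.23 as a mean of per-cell CPM. Smooth muscle or pericyte-like cells had 0 Ncf1 UMIs in both libraries, where 3 counts would give 2.10 CPM in WT and 1.65 in KI. For type 1 alveolar cells 3 counts would give 1.71 and 2.59 CPM.

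**Figure D1:**
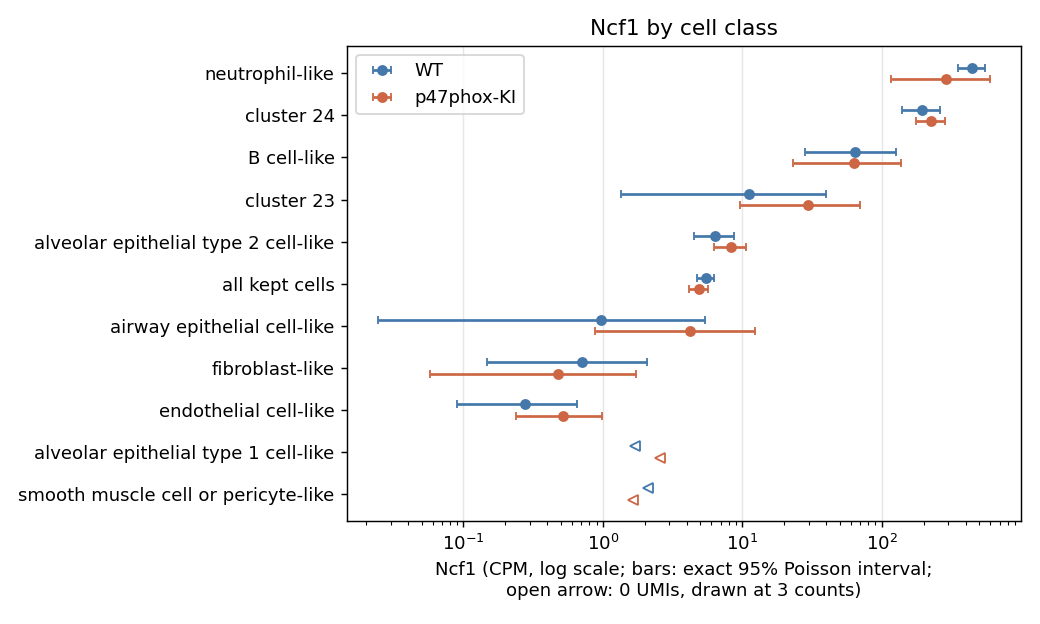
Ncf1 level per cell class in CPM on a log axis for the WT and p47phox-KI libraries, with exact 95% Poisson intervals, and open arrows at 3 counts where no UMI was found. Neutrophil-like cells lie at 444 (WT) and 290 CPM (KI) with overlapping intervals, while endothelial-like cells lie at 0.278 and 0.519 CPM.

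Among the partners of p47phox, Ncf4 (p40phox) was lower in KI leukocyte clusters, with 85 and 34 UMIs and a log2 ratio of −1.10 [−1.71, −0.51]. By cluster the Ncf4 ratio was −0.10 [−1.61, 1.13] in neutrophil-like cells, −0.93 [−1.87, −0.0087] in cluster 24, −0.71 [−2.93, 1.27] in cluster 23 and 0.70 [−1.51, 3.04] in B cell-like cells. Cybb (gp91phox), a membrane subunit, had a pooled leukocyte ratio of 0.36 [0.11, 0.61] but a ratio of −0.26 [−0.52, 0.0048] in cluster 24, which held 224 of 258 WT and 271 of 283 KI leukocyte UMIs of the gene. Cyba (p22phox), the other membrane subunit, read higher in KI over all leukocyte clusters, at 0.56 [0.37, 0.75], and in cluster 24, at 0.40 [0.16, 0.64]. The small GTPase gene Rac2 had a pooled ratio of −0.28, but 0.87 [0.21, 1.54] in B cell-like cells, 0.22 [−0.20, 0.63] in cluster 23, 0.0059 [−0.69, 0.71] in cluster 24 and −0.39 [−1.30, 0.41] in neutrophil-like cells. These leukocyte sums mix different cell types, since neutrophil-like cells were 96 of 241 leukocytes in WT and 11 of 127 in KI. Nox4, an oxidase that works without p47phox, was higher in KI fibroblast-like cells, at 257 CPM in WT and 349 in KI, a ratio of 0.44 [0.33, 0.56]. A Nox4 UMI was found in 42.1% of WT and 56.0% of KI fibroblast-like cells at median depths of 2365 and 2773 UMIs, against 0.990% and 1.72% of endothelial-like cells at the depths given above. In smooth muscle or pericyte-like cells Nox4 was also higher in KI, by 0.76 [0.20, 1.33]. Nox4 read 1.90 higher in KI type 1 alveolar cells, whose WT level (8.57 CPM) was more than 20 times lower than in fibroblast-like cells, and, at a free-RNA level, 1.83 higher in type 2 alveolar cells, which became 0.36 and 0.34 with doublets kept. The endothelial-like Nox4 ratio of 0.91 also lay at a free-RNA level and turned to −0.99 when each library was clustered alone.

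The 2 libraries also differed in sex-linked transcripts, which bears on every leukocyte value. The 4 Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d gave 5 UMIs in the WT library and 185 in the KI library. In KI, 70 of 127 leukocytes (55.1% [46.0, 63.9], exact interval) held such a UMI, against 17 of 6509 other kept cells (0.261%). In WT, 2 of 241 leukocytes did (0.830%). Xist, the transcript of the inactive X chromosome, was found in 53.9% of WT and 15.7% of KI leukocytes. Outside the leukocyte clusters Xist was found in 85.5% of WT and 88.4% of KI cells. The comparison of leukocytes therefore sets cells with different sex-linked transcripts against each other. This bears on Ncf1 too, since leukocyte clusters held 90 of its 162 KI UMIs in kept cells. Whether all KI leukocytes carry the modified gene cannot be told from these values.

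**Figure D2:**
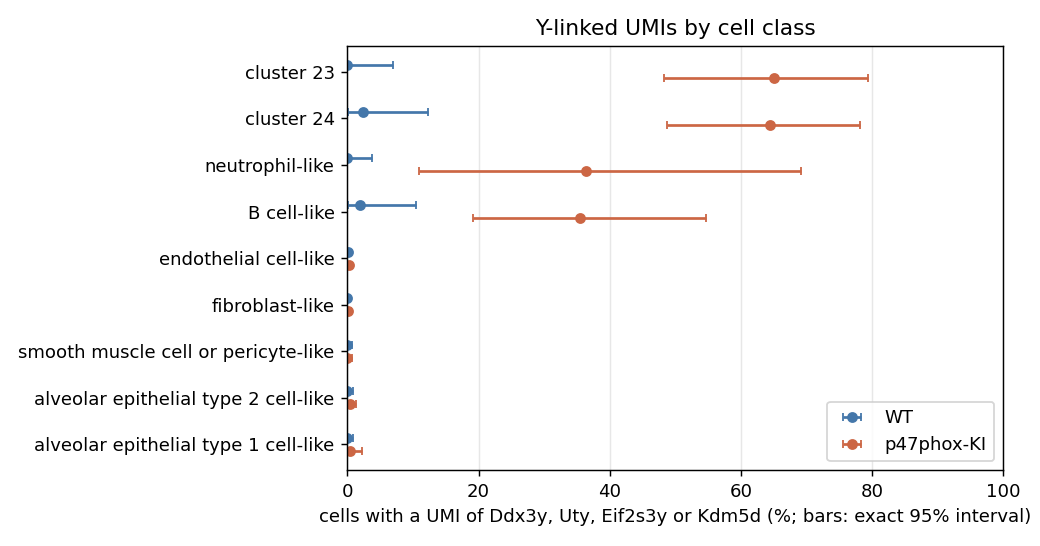
Percentage of kept cells with a UMI of Ddx3y, Uty, Eif2s3y or Kdm5d in each leukocyte cluster and each compared class, per library, with exact 95% binomial intervals. In KI, cluster 23 stands at 65.0%, cluster 24 at 64.4%, neutrophil-like cells at 36.4% and B cell-like cells at 35.5%. KI endothelial-like cells stand at 0.312%, and WT leukocyte clusters at 2.33% or less.

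The next question is which cell classes the 2 libraries held. Endothelial-like cells, which line the vessels, made up 58.8% [57.7, 59.9] of kept WT cells and 58.0% [56.8, 59.2] of KI cells. Fibroblast-like cells made up 18.3% and 17.9%. Neutrophil-like cells, leukocytes that enter an injured lung early, were scarcer in the KI library, at 96 cells (1.24% [1.01, 1.51]) in WT and 11 cells (0.166% [0.0828, 0.296]) in KI. The log2 ratio of these shares was −2.90 [−3.95, −2.00]. The other leukocyte clusters together made up 1.87% of WT and 1.75% of KI cells, a ratio of −0.10 [−0.47, 0.26], and B cell-like cells 0.659% and 0.467%, a ratio of −0.50 [−1.19, 0.17].

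Among structural cells, smooth muscle or pericyte-like cells were 6.49% of WT and 8.03% of KI cells, a log2 ratio of 0.31 [0.13, 0.49]. Type 2 alveolar cells, which make surfactant, were 5.86% and 8.59%, a ratio of 0.55 [0.37, 0.73]. Of these, a cluster of low depth held 3 WT and 93 KI cells. Type 1 alveolar cells, the flat cells of gas exchange, were 5.60% and 3.83%, a ratio of −0.55 [−0.78, −0.32]. Airway epithelial-like cells were 0.814% and 0.693%, and mesothelial-like cells 0.142% and 0.136%. Unnamed clusters held 2.16% of WT and 2.23% of KI cells. They were cluster 20, led by Hhip, Cyp2e1 and Ccl7, cluster 23, a mixture led by the T cell and natural killer genes Ccl5, Gzma and Cd3d, cluster 24, and a small neural cluster 32 with Prph. All shares are shares of sorted cells after a CD45.2 stain with an unstated gate, above a floor of 500 UMIs and at median depths of 3307 and 3774.5 UMIs. They are not shares of the lung, and a single library per group cannot separate genotype from preparation.

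**Figure D3:**
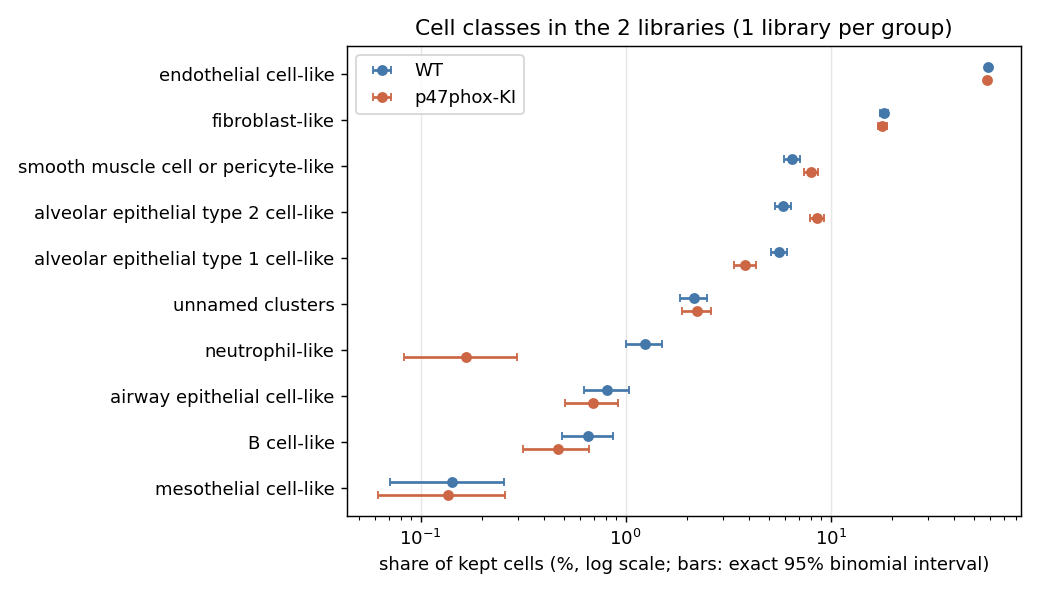
Share of kept cells in each class of the WT and p47phox-KI libraries, in percent on a log axis, with exact 95% binomial intervals. Neutrophil-like cells stand at 1.24% in WT and 0.166% in KI, while endothelial-like cells stand at 58.8% and 58.0%.

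In endothelial-like cells (4546 WT, 3848 KI), the retinoic acid-degrading enzyme gene Cyp26b1 was far lower in the KI library, and the interferon-induced genes Oasl2 and Ifit1 and the heat-shock gene Hspa1b were higher. Cyp26b1 (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908) stood at 106 CPM in WT and 17.2 in KI, a log2 ratio of −2.62 [−2.81, −2.45]. Oasl2, an interferon-induced antiviral gene, stood at 47.7 and 107 CPM (1.17 [1.05, 1.28]), and Ifit1 at 32.0 and 65.9 CPM (1.04 [0.90, 1.19]). Hspa1b, an inducible heat-shock protein gene, stood at 225 and 530 CPM (1.23 [1.18, 1.29]).

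The 10 lowest ratios in endothelial-like cells also included Nckap5 (−1.65), Arhgap28 (−1.32), Fbxw10 (−1.31), Tmem252 (−1.22), the chemokine-scavenging receptor gene Ackr3 (−1.10), Tbc1d8 (−1.08), Sh3pxd2a (−1.07), the activin subunit gene Inhbb (−1.05) and Apold1 (−1.04, or −1.72 at resolution 0.5). Tmem252, Inhbb and Ackr3 lead endothelial cluster 5, which held 501 WT and 109 KI cells. Apold1 and heat-shock genes lead cluster 6, which held 223 WT and 365 KI cells, a difference opposite in direction to the Apold1 ratio. With the same cluster weights in both libraries the ratios were −0.89 for Tmem252, −0.63 for Inhbb, −0.98 for Ackr3, −2.77 for Cyp26b1, 1.21 for Oasl2 and 0.74 for Hspa1b. The 10 highest also included the sulfotransferase gene Sult1a1 (1.28), Ccdc28b (1.19), the Hippo pathway kinase gene Stk4 (1.14), the endothelial transcription factor gene Sox18 (1.09), Serpinb6b (1.05), the growth-arrest gene Gadd45a (1.03) and Card10 (1.01).

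Interferon-induced genes were read as a pair of lists in endothelial-like cells. Of 26 measured members of the type I interferon list, 8 were more than 0.5 higher and 0 more than 0.5 lower, with a median of 0.30 [counting range 0.20, 0.38] at percentile 100 of random lists. Ifit3b stood at 0.77. The interferon gamma list had the same median of 0.30 (percentile 99.9), with 3 of 17 members higher, 2 lower and 12 between. At resolution 0.5 the medians were 0.12 for the type I list and 0.022 for the interferon gamma list. Its largest ratios were Gbp6 (0.84), the chemokine gene Cxcl9 (−0.89, or −0.12 with no cell filter) and Ciita (−0.63, or 0.01 as a mean of per-cell CPM). The immediate-early and dissociation stress list, which holds heat-shock and AP-1 genes, had a median of 0.40 [0.34, 0.43] at percentile 100, with 9 of 25 members higher and 1 lower. Hspa1a and Hsph1 both stood at 0.81.

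Of 17 measured endoplasmic reticulum stress genes in endothelial-like cells, 6 were more than 0.5 lower and 0 higher, with a median of −0.29 [−0.36, −0.23] at percentile 0. The chaperone genes Calr (−0.59), Hspa5 (−0.58) and Creld2 (−0.58) were furthest. Glycolysis and hypoxia genes had a median of −0.12 [−0.16, −0.04] at percentile 0.85, with 3 of 21 lower. Pfkl stood at −0.57, and Hk2 (−0.59, or −1.50 with each library clustered alone) and Slc16a3 (−0.51) were at free-RNA levels. Endothelial adhesion and barrier genes had a median of −0.21 [−0.22, −0.13] at percentile 0.09, with 1 of 17 members higher and 0 lower. The selectin genes Sele (1.25, or −2.98 at resolution 0.5) and Selp (−0.50, or 2.01 with each library clustered alone) and the leukocyte ligand gene Vcam1 (0.41, or −0.33 at resolution 0.5) had no stable direction.

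Chemokine genes in endothelial-like cells had a median of −0.20 at percentile 1.99, with 3 of 10 members lower and 1 higher. The lymphocyte attractant gene Cxcl10 stood at −1.01 (−0.32 with no cell filter) and Ccl5 at 1.64 (0.47 as a mean of per-cell CPM). Ccl5 leads the unnamed cluster 23, which the free-RNA limit does not cover, so RNA from those cells may enter its ratio. The cell cycle list had a median of 0.36 [0.21, 0.46] at percentile 99.8, with 10 of 24 members higher. A small endothelial-like cluster 29, led by cell cycle genes such as Cenpf, held 11 WT and 22 KI cells. Ccnb1 stood at 2.11, Rrm2 at 1.81 and Cenpf at 1.79. With the same cluster weights, a setting that also leaves cluster 29 out, Ccnb1 became −1.27, Rrm2 0.32 and Cenpf −0.45. The list's median became −0.13. No alternative left out cluster 29 alone, so its part was not tested. The matrix and fibrosis list had a median of 0.24 at percentile 98.0, with 3 of 15 members higher and 2 lower. This median was −0.27 with each library clustered alone. Its furthest members, Mmp2 (0.71), Timp1 (−0.63) and Tnc (−0.58, or 1.93 at resolution 0.5), were at free-RNA levels.

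In fibroblast-like cells (1413 WT, 1186 KI), the enzyme gene Ch25h, the matrix gene Thbs1 and the chemokine gene Ccl2 were lower in the KI library, and the proteoglycan genes Lum and Omd were higher. Medians of the glycolysis, redox, NF-kB and chemokine lists lay below 0, though most measured glycolysis, redox and NF-kB members stayed within 0.5 of 0. Ch25h (ENSMUSG00000050370, chromosome 19, 34473778 to 34475164), which encodes cholesterol 25-hydroxylase, stood at 170 CPM in WT and 31.2 in KI, a log2 ratio of −2.44 [−2.72, −2.17]. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, stood at 3092 and 874 CPM (−1.82 [−1.88, −1.77]). Lum, which encodes the collagen-binding proteoglycan lumican, stood at 103 and 364 CPM (1.81 [1.66, 1.97]).

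Other low ratios in fibroblast-like cells were Spon2 (−1.67, or −1.01 under the stricter filter), Rhbdd2 (−1.66), the cAMP phosphodiesterase gene Pde4b (−1.58), Wisp2 (−1.44), Gcnt2 (−1.44), the polyamine synthesis gene Odc1 (−1.41), Bcr (−1.40) and the retinol-storing enzyme gene Lrat (−1.39). Other high ratios were the proteoglycan gene Omd (1.31), Pnpla7 (1.28), the lipid droplet gene Plin3 (1.26), Fam13a (1.26), Sult1a1 (1.18), Ccdc80 (1.18), the clock-controlled transcription factor gene Tef (1.14) and Acss3 (1.13). Thbs1 leads fibroblast cluster 12, Lum leads cluster 15 and Lrat leads cluster 16, and the libraries filled clusters 12 and 15 unequally. With the same cluster weights the ratios were −1.40 for Thbs1, 1.05 for Lum, −1.30 for Lrat and −2.12 for Ch25h.

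Chemokine genes in fibroblast-like cells had a median of −0.40 [−0.63, −0.05] at percentile 0.05, with 5 of 10 members more than 0.5 lower and 3 higher. The monocyte attractant gene Ccl2 had 738 UMIs in WT and 163 in KI (−2.18 [−2.43, −1.93], or −2.79 without clusters of low depth). Ccl7 stood at −1.84 and the B cell attractant gene Cxcl13 at 1.75 (0.94 with the same cluster weights). The NF-kB list had a median of −0.22 [−0.32, −0.16] at percentile 0.295, with 3 of 17 members lower and 2 higher. Bcl3 stood at −1.02, Cd40 at −0.95 and the prostaglandin synthase gene Ptgs2, at a free-RNA level, at 1.13 (0.33 with no cell filter). Redox and NRF2 genes had a median of −0.20 [−0.27, −0.15] at percentile 0.17, with 7 of 25 members lower and 0 higher. The thioredoxin reductase gene Txnrd1 stood at −1.24, the superoxide dismutase gene Sod2 at −0.83 and the cystine transporter gene Slc7a11, at a free-RNA level, at −1.30 (−1.89 as a mean of per-cell CPM).

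Glycolysis and hypoxia genes in fibroblast-like cells had a median of −0.29 [−0.40, −0.19] at percentile 0, with 6 of 21 members more than 0.5 lower and 0 higher. Hif1a, the oxygen-regulated transcription factor gene, stood at −0.93 and the hexokinase gene Hk2 at −0.90. The lactate transporter gene Slc16a3 stood at −1.24 (−1.88 under the stricter filter), at a free-RNA level. Endoplasmic reticulum stress genes had a median of −0.21 at percentile 0.58, with 3 of 17 members higher and 3 lower. Manf stood at −0.80, Ddit3 at 0.69 and Trib3 at 0.70. Endothelial adhesion and barrier genes, read here in a class that should hold few of them, had a median of −0.27 at percentile 0.07, with 4 of 14 members lower and 0 higher. Angpt2 stood at −0.66, and Plvap (−0.58, or −1.16 with doublets kept) and S1pr1 (−0.54) were at free-RNA levels. That median was 0.19 as a mean of per-cell CPM.

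Alternative activation and resolution genes in fibroblast-like cells had a median of 0.45 [0.12, 0.55] at percentile 99.5, with 4 of 11 members more than 0.5 higher and 2 lower. Their furthest members are macrophage genes at low counts here, Chil3 with 5 and 18 UMIs (1.85) and Mgl2 with 18 and 36 UMIs (1.00). Chil3 leads the unnamed macrophage cluster 24, which the free-RNA limit does not cover, so RNA from those cells may enter the Chil3 ratio. Spp1, at a free-RNA level, stood at 1.04 (0.17 as a mean of per-cell CPM). The type I interferon list had a median of 0.32 [0.23, 0.52] at percentile 98.4, with 10 of 24 members higher and 1 lower. Rsad2 stood at 1.23 (−0.15 under the stricter filter), Cmpk2 at 1.09 and Oas2 at 1.00.

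In smooth muscle or pericyte-like cells (502 WT, 533 KI), the metallothionein genes Mt1 and Mt2, Thbs1 and the endoplasmic reticulum gene Sdf2l1 were lower in the KI library, and the sulfotransferase gene Sult1a1 was higher. Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), which encodes a metal-binding stress protein, stood at 6373 CPM in WT and 2999.9 in KI, a log2 ratio of −1.09 [−1.14, −1.04]. Its neighbour Mt2 stood at −1.17 [−1.26, −1.08]. Thbs1 stood at 575 and 220 CPM (−1.38 [−1.56, −1.21]).

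Other low ratios in smooth muscle or pericyte-like cells were the endoplasmic reticulum gene Sdf2l1 (−1.44 [−2.02, −0.88]), Mphosph10 (−1.29), Atp9b (−1.15, or −1.75 under the stricter filter), Tnfrsf12a (−1.12), Odc1 (−1.11) and Stc1 (−1.10). Other high ratios were Zfyve21 (1.30), Bcl9l (1.28), the forkhead gene Foxs1 (1.24), Sult1a1 (1.20), Mnd1 (1.20), the heat-shock gene Hsph1 (1.17, or 1.91 as a mean of per-cell CPM), Mospd1 (1.16), Marcksl1 (1.13) and Gcc2 (1.10). Metallothionein ratios varied over the classes. Mt1 stood at −1.56 [−1.61, −1.51] in endothelial-like cells (−0.997 with the same cluster weights), −0.72 in fibroblast-like cells, −0.47 in type 1 and −0.08 in type 2 alveolar cells. The WT endothelial-like level of Mt1 was 4.69% of the WT fibroblast-like level, and both this and the type 1 alveolar value are at free-RNA levels.

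Endoplasmic reticulum stress genes in smooth muscle or pericyte-like cells had a median of −0.36 [−0.45, −0.27] at percentile 0, with 6 of 16 members more than 0.5 lower and 0 higher. After Sdf2l1, Creld2 (−0.998) and Manf (−0.67) were furthest. Glycolysis and hypoxia genes had a median of −0.14 [−0.30, −0.03] at percentile 2.00, with 3 of 19 lower and 1 higher. Pfkfb3 stood at −1.05, Hif1a at −1.03 and the glucose transporter gene Slc2a1 at 0.65 (0.04 with no cell filter). This median was 0.02 under the stricter filter. Matrix and fibrosis genes had a median of 0.20 [0.02, 0.25] at percentile 99.3, with 1 of 15 members higher. The gelatinase gene Mmp2 stood at 0.65, Tnc at 0.49 (1.61 under the stricter filter) and Lox, at a free-RNA level, at −0.43. Endothelial adhesion and barrier genes had a median of −0.29 [−0.46, −0.07] at percentile 0.17, with 3 of 13 lower and 2 higher. Vwf stood at 1.35 (−1.24 under the stricter filter), Tjp1 at 0.56 and Icam2, at a free-RNA level, at −0.71 (−1.83 under the stricter filter).

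**Figure D4:**
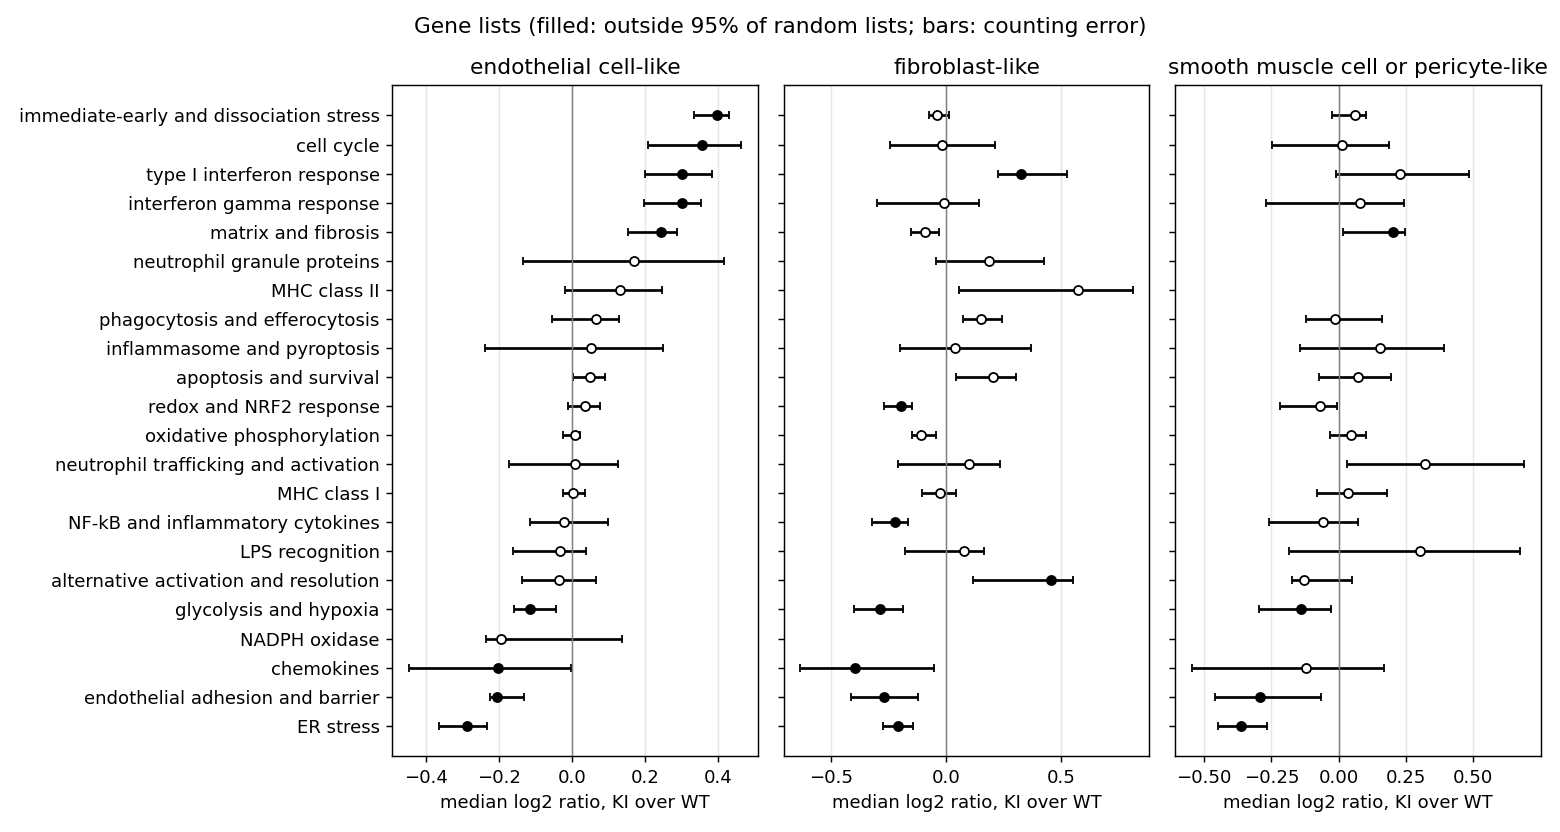
Median log2 ratio (KI over WT) of gene lists in endothelial-like, fibroblast-like and smooth muscle or pericyte-like cells, with bars for counting error and filled points for medians outside 95% of random lists. Lists with fewer than 5 measured members in the class or in endothelial-like cells are not drawn. The lists of sex, cell damage and free haemoglobin RNA are also left out. The medians of the endoplasmic reticulum stress list lie below 0 in each of the 3 classes, at −0.29, −0.21 and −0.36.

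Over the 27 lists, 4 of 26 with a median in endothelial-like cells lay below the central 95% of random lists and 6 above it. In fibroblast-like cells these counts were 6 and 3 of 25, and in smooth muscle or pericyte-like cells 4 and 2 of 25. In type 2 alveolar cells they were 5 and 4 of 25, and in type 1 alveolar cells 4 and 9 of 25. These counts include the lists of free haemoglobin RNA and of cell damage, which read preparation and quality. Free haemoglobin RNA lay at percentile 0 in type 1 alveolar cells and at percentile 100 in every other compared class. The cell damage list lay above the central 95% in type 1 alveolar cells only. The NADPH oxidase list had a median of −0.19 in endothelial-like cells, at percentile 7.17 with 5 members measured, and reached 0.089 over the alternatives. In type 2 alveolar cells it was 0.14, at percentile 51.45 with 6 members. With 3 members each, it was −0.30 in fibroblast-like, −0.13 in smooth muscle or pericyte-like and 0.18 in type 1 alveolar cells. Differences between classes were not tested.

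In type 2 alveolar cells (453 WT, 570 KI), Osgin1 and Srxn1, both targets of the oxidative stress regulator NRF2, were lower in the KI library, at −1.23 [−1.40, −1.07] and −1.09. Of 25 measured redox and NRF2 genes, 6 were more than 0.5 lower, 0 higher and 19 between, with a median of −0.13 [−0.19, −0.09] at percentile 0.01. Slc7a11, at a free-RNA level, stood at −0.95 (−2.40 under the stricter filter). The lowest ratios by the naming rule were Osgin1, the linker histone gene Hist1h1c (−1.44 [−1.65, −1.24]) and Rhou (−1.33). The highest were the chromatin remodeller gene Chd9 (1.45 [1.25, 1.64]), Retnla (1.29 [1.12, 1.46]) and Piwil4 (1.04). A Retnla UMI was found in 16.6% of WT and 16.1% of KI cells, at median depths of 12881 and 12937 UMIs, so the share of cells did not rise. Retnla is also a leading gene of the airway epithelial-like cluster 28. Immediate-early and dissociation stress genes had a median of 0.25 [0.23, 0.28] at percentile 100, with 3 of 25 higher, led by the transcription factor genes Klf2 (0.64) and Egr2 (0.64) and the chaperone gene Dnajb1 (0.59). Endoplasmic reticulum stress genes had a median of −0.09 [−0.15, −0.02] at percentile 1.89, which became 0.02 as a mean of per-cell CPM. Of their 17 members, 1 was higher and 1 lower, with Trib3 at 0.70 (0.10 under the stricter filter), Xbp1 at −0.54 and Manf at −0.39.

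In type 1 alveolar cells (433 WT, 254 KI), the AP-1 gene Fosl1 and the NRF2 target gene Osgin1 were lower in the KI library. This class also differed in quality, with median depths of 2995 UMIs in WT and 2502 in KI and median mitochondrial shares of 4.23% and 4.84%. The list of mitochondrial and nuclear transcripts that mark cell damage had a median of 0.28 in it, at percentile 98.8. Fosl1 had 128 UMIs in WT and 9 in KI (−3.24 [−4.40, −2.27]), Osgin1 stood at −2.56 [−3.03, −2.12] and Arid5a at −1.96 (−0.99 with doublets kept). Of 14 measured NF-kB genes, 8 were more than 0.5 lower and 1 higher, with a median of −0.68 [−0.87, −0.48] at percentile 0. Bcl3 stood at −2.08 (−0.83 with doublets kept), Relb at −1.29 (−1.90 under the stricter filter) and Tnfaip3, at a free-RNA level, at −1.19 (−0.37 with doublets kept). Redox and NRF2 genes had a median of −0.31 [−0.43, −0.21] at percentile 0.02, with 6 of 24 lower, 1 higher and 17 between. The haem oxygenase gene Hmox1 stood at −1.56 (−2.74 under the stricter filter) and Nqo1 at 1.43 (−0.84 under the stricter filter). Unlike in the other compared classes, the endoplasmic reticulum stress median lay above 0, at 0.12 [0.02, 0.23] and percentile 84.9. Of its 16 measured members, 2 were higher and 0 lower, and the median ranged from −0.03 to 0.17 over the alternatives.

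The type I interferon list in type 1 alveolar cells had a median of 0.34 [0.06, 0.55] at percentile 98.3, with 6 of 21 members more than 0.5 higher and 1 lower. Slfn5 stood at 2.04 (1.01 with doublets kept), Isg15 at 1.42 (0.51 as a mean of per-cell CPM) and Rsad2 at 1.32 (3.44 under the stricter filter). The highest ratios in this class belonged to genes of other cell types and depended on doublets. Mgp stood at 2.75, Tmem204 at 2.75 and the stem cell factor gene Kitl at 2.71, and with doublets kept these were 0.21, 0.97 and 1.00. Matrix and fibrosis genes had a median of 1.97 [1.25, 2.41] at percentile 100, with 7 of 13 members higher and 1 lower. Col1a1 stood at 3.73 (0.56 with doublets kept), and Mmp2 at 2.82 (0.05) and Col1a2 at 2.77 (0.37), both at free-RNA levels. This median became 0.09 with doublets kept and −0.14 under the stricter filter. Endothelial adhesion and barrier genes had a median of 1.21 [1.06, 1.40] at percentile 100, with 9 of 13 higher and 3 lower, and 0.20 with doublets kept. Vcam1 stood at 2.74 (−0.44 with doublets kept), Tek at 2.07 (0.48) and Icam2 at 1.87 (0.45).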

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

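The explanations for the scarce neutrophil-like cells, and the comparison of Mt1 with fibroblast markers, were chosen only after the result was seen, and all other tests in this part were stated before their values were computed. Several lists had opposite directions in different cell classes, and none of these differences was tested. Chemokine genes stood at 0.37 in type 2 alveolar cells and −0.40 in fibroblast-like cells, 0.77 apart on the log2 scale, but over the alternatives they came as near 0 as 0.068 and −0.057. Endothelial adhesion and barrier genes stood at 1.21 in type 1 alveolar cells and −0.29 in smooth muscle or pericyte-like cells, 1.499 apart, but the first became 0.20 with doublets kept. Neutrophil granule genes stood at 1.10 in type 1 alveolar cells and −0.60 in smooth muscle or pericyte-like cells, 1.70 apart, but these rest on 4 and 3 measured members, and became −0.78 with doublets kept and 0.019 as a mean of per-cell CPM. Free haemoglobin RNA stood at 8.67 in fibroblast-like cells and −3.31 in type 1 alveolar cells, 11.98 apart. In type 1 alveolar cells the WT level came from few cells, since Hbb-bs was found in 0.462% of WT and 9.84% of KI cells but with 1924 and 76 UMIs. A signal outside the compared classes was a group of 46 erythroid-like barcodes in the unfiltered KI library, against 2 in WT. No cluster of filtered cells was named erythroid-like, but whether single barcodes of this group passed the filter was not followed. Among kept cells, 3 WT and 12 KI barcodes held over 1% haemoglobin UMIs. Another signal was the 185 Y-linked UMIs of the KI library, against 5 in WT.

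Neutrophil-like cells were scarcer in the KI library (96 cells in WT and 11 in KI). A stricter CD45 gate that removed all leukocytes alike predicts that the other leukocytes are as much scarcer, but their log2 ratio was −0.10 [−0.47, 0.26]. This argues against such a gate for the sorted leukocytes as a whole, but many of the KI ones held Y-linked UMIs (65.0% of cluster 23, 64.4% of cluster 24), so the effect of the gate on the lung's own leukocytes stays open. The filter on detected genes and mitochondrial share also could have removed them, but without it the ratio was −2.97 [−4.02, −2.07], from 99 and 11 cells, which argues against that too. No biological explanation was tested, and 4 of 11 KI against 0 of 96 WT neutrophil-like cells held a Y-linked UMI, so their origin is open as well, and genotype, animal and preparation coincide with the library.

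The type I interferon list stood higher in KI endothelial-like cells, with a median of 0.30 that was 0.12 at resolution 0.5. With the same cluster weights in both libraries the median was 0.35, which argues against the mix of the 10 weighted endothelial clusters as the cause. That weighting keeps to a single clustering, so it cannot test which cells make up the class. The 0.12 at resolution 0.5 leaves that open. RNA from other cells predicts that many measured members lie at a free-RNA level, but only 3.85% (1 of 26) did. This comparison covers named classes only, and not the leukocyte clusters 23 and 24. It also cannot detect stray RNA of genes that many classes express, so RNA from other cells stays open. In the 2896 WT and 1993 KI endothelial-like cells with no UMI of 4 heat-shock genes the median was 0.35 [0.27, 0.46]. That argues against cells with detected RNA of these 4 genes as the source. A cell can express them undetected, so a difference in the response to dissociation stays open. A genotype effect may be followed up, though 1 library per group leaves the animal, its sex-linked leukocyte difference and the time of harvest inseparable from it.

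Mt1 stood lower in several KI classes. A different time of day at harvest predicts that 9 and 4 clock genes of opposite phase move apart by more than 1, but the farthest difference among 5 classes was 0.59, which leaves it undecided. With the same cluster weights the Mt1 ratio in endothelial-like cells was −0.997 (−1.56 unweighted), which leaves the mix of clusters undecided. The WT endothelial-like level of Mt1 was 4.69% of the level in the highest class, in line with RNA spread from other cells, but fibroblast markers reached only 0.429% to 1.24% of their fibroblast-like level there, so fibroblast RNA alone is an unlikely source. In smooth muscle or pericyte-like cells the Mt1 ratio was −1.09, or as near 0 as −0.57 over the alternatives. The WT level of Mt1 there was 43.7% of the fibroblast-like level, above the free-RNA limit. A genotype effect or a difference in stress may account for the lower Mt1 in this class.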

How the results depend on the processing

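No paired analysis was possible because each group holds 1 library. A value is called reversed here only if it changed sign and its main interval excluded 0, and for a list also only if the main median lay outside the central 95% of random lists. Over all alternatives, class shares kept their value within counting error in 46 cases and moved in 7, and none reversed. For list medians 1457 stayed, 241 moved and 15 reversed, and for named genes 1767 stayed, 203 moved and 19 reversed. Signs also turned for values not past those limits, in 5 cases for the endothelial-like and fibroblast-like shares, 143 for 49 list medians, 2 for Ncf1 and 10 for 5 named genes, among them endothelial-like Tnc (1.93 at resolution 0.5). Where a value moved or reversed the cause was not tested. The neutrophil-like share ratio ranged from −2.99 to −2.79, but with each library clustered alone no KI cluster was neutrophil-like, so that setting gave no value. The leading list medians ranged from −0.34 to −0.23 (endothelial-like ER stress), 0.14 to 0.42 (endothelial-like immediate-early), −0.39 to −0.24 (fibroblast-like glycolysis), 0.12 to 0.55 (fibroblast-like alternative activation), −0.41 to −0.33 (smooth muscle ER stress) and 0.17 to 0.24 (smooth muscle matrix). The type I interferon median ranged from 0.12 to 0.41 in endothelial-like, 0.088 to 0.50 in fibroblast-like, 0.019 to 0.52 in smooth muscle, 0.038 to 1.29 in type 2 and 0.22 to 0.56 in type 1 alveolar cells, and the endothelial-like interferon gamma median from 0.022 to 0.46. The number of cells limits the KI neutrophil-like values, which rest on 11 cells.

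Share ratios moved as follows: endothelial-like to 0.076 with doublets kept, −0.16 at resolution 0.5 and 0.046 with each library alone; fibroblast-like to −0.15 and smooth muscle to 0.57 under the stricter filter; type 2 alveolar to 0.35 and type 1 to −0.78 without clusters of low depth. Ncf1 in kept cells moved to −1.38 as a mean of per-cell CPM and 0.38 with the same cluster weights. Thinned to 1000 UMIs, the median genes per cell were 689 in WT and 693 in KI. The endothelial-like immediate-early median moved to 0.21 at resolution 0.5 and 0.14 with the same weights.

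Reversed list medians were, in endothelial-like cells, cell cycle (−0.089 strict, −0.081 at resolution 2, −0.13 weighted) and matrix (−0.27 alone); fibroblast-like adhesion (0.19 per cell); smooth muscle granule (0.019 per cell) and glycolysis (0.024 strict); type 2 alveolar trafficking (0.32 per cell), ER stress (0.017 per cell) and complement (−0.17 doublets kept). In type 1 alveolar cells with doublets kept, granule (−0.78), trafficking (0.015, or 0.42 with no minimum) and complement (−0.24) reversed, and matrix did under the stricter filter (−0.14).

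Reversed genes in endothelial-like cells were Nox4 (−0.99 alone), Ciita (0.015 per cell), Cenpf (−0.087 at resolution 2, −0.45 weighted), Ccnb1 (−0.73 strict, −0.93 at resolution 2, −1.27 weighted), Sele (−2.98) and Vcam1 (−0.33) at resolution 0.5, and Selp (0.31 doublets kept, 0.25 strict, 2.01 alone). Elsewhere they were fibroblast-like Rsad2 (−0.15 strict), smooth muscle Vwf (−1.24 strict, −0.31 per cell), and in type 1 alveolar cells Nqo1 (−0.84 strict), Vcam1 (−0.44 doublets kept) and Col1a2 (−0.38 strict, −0.45 without clusters of low depth).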

Other observations

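All comparisons for the hypothesis below were chosen only after the result was seen. Interferon-induced genes were measured in each remaining class. In type 2 alveolar cells the type I interferon list had a median of 0.44 at percentile 96.8, with 9 of 19 members more than 0.5 higher and 0 lower in KI. That median ranged from 0.038 under the stricter filter to 1.29 as a mean of per-cell CPM. In smooth muscle or pericyte-like cells its median was 0.23 at percentile 91.1, and 0.019 under the stricter filter. Differences between classes were not tested. Mitochondrial respiration genes barely differed in endothelial-like cells, with a median of 0.01 for the oxidative phosphorylation list.

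Mt2 stood at −0.61 in fibroblast-like cells and 0.00 in type 2 alveolar cells.

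Y-linked UMIs were found in leukocytes of the KI library. They were found in 65.0% of cells in cluster 23, 64.4% in cluster 24, 36.4% of neutrophil-like cells (4 of 11) and 35.5% of B cell-like cells. A hypothesis is that cells of a male lung were mixed into the KI library. Outside the leukocyte clusters the 4 Y-linked genes gave 0.707 CPM [0.448, 1.06], against 226 CPM [190, 267] in leukocyte clusters, which argues against a whole male lung. A candidate explanation is male leukocytes among cells of female lungs, as after a transfer of leukocytes or bone marrow. An Xist UMI was found in 11.4% [5.07, 21.3] of the 70 KI leukocytes with a Y-linked UMI and in 21.1% [11.4, 33.9] of the 57 without. KI leukocytes without a Y-linked UMI may be male cells in which none was detected, so this comparison cannot decide the hypothesis. Both shares lie below the 53.9% [47.4, 60.4] of WT leukocytes. Median depth was 4285.5 UMIs in KI leukocytes with a Y-linked UMI, 2986 in those without and 2122 in WT leukocytes. By cluster, Xist was found in 35 of 51 WT and 3 of 40 KI cells of cluster 23. In cluster 24 these counts were 36 of 43 and 9 of 45, and in B cell-like cells 37 of 51 and 6 of 31. Neutrophil-like cells, with 22 of 96 and 2 of 11, did not separate the libraries. Outside neutrophil-like cells the lower KI shares go with male cells among the KI leukocytes. How such cells came into the library was not tested, so a transfer stays open.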
